A study of Homo sapiens with 7 samples.

How the data were processed

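The samples were chromatin immunoprecipitations from MCF-7 cells and 1 input sample, grouped by the antibody named in each sample title: IgG, RECQ1 and ERα with 2 replicates each. Per the labels, cells were crosslinked with formaldehyde, chromatin was sheared by sonication and enriched with a ChIP-IT kit, and libraries made with a TruSeq kit were sequenced from a single end on a NextSeq instrument. The antibody tags of IgG replicate 1 and RECQ1 replicate 1 name histone-mark antibodies, contrary to the sample titles and to the extraction protocol. The titles were followed, and if those tags were right the RECQ1 replicate 1 list would hold another mark, and both replicate 1 lists, ERα included, would have been called against a histone-mark library in place of IgG. The description of IgG replicate 1 also names the peak list of ERα replicate 1, which was taken as ERα from its own name. Per the labels, the passage range of RECQ1 and ERα replicate 1 is higher than that of IgG replicate 1. Nothing in the labels says that replicates came from separate cultures, so differences between them may be technical.

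Peaks were called with MACS2 on hg19, per the submitters' processing notes. The deposited lists are broad peaks of 1 ChIP library against the IgG library of the same replicate number, as they are named; replicates were not pooled. The aligner, the MACS2 version, the read filters and the peak threshold are not given in the sources used here. Peaks were used from the 4 per-replicate lists and from 1 deposited list of shared RECQ1 peaks. The IgG and input samples entered only through the authors' peak calling, and reads and signal were not analysed here.

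Each deposited peak has a position and values given by the authors' peak caller. Column 5 is a score, used here as deposited; it equals 10 times column 9 with decimals dropped in every peak of 3 lists and in all but 1 peak of RECQ1 replicate 2. In every peak of the lists column 9 exceeded column 7 and column 7 exceeded column 8, an order that the usual layout of fold, p and q cannot give. Columns 7, 8 and 9 were therefore treated as scores of unsettled meaning. Scores were compared only within a list, except in naming regions, which were ranked by the lower of the replicates' scores. Spearman correlations across peaks between the score and columns 7 and 8 were at least 0.988. The design had named fold enrichment; as foreseen in it, the score took its place, and the higher-scoring 50% of each list took the place of a stricter q threshold.

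Depth per sample was unknown, so no precision could be derived from reads. Shares of peaks carry 95% Wilson intervals, which cover counting error over peaks and not variation between cultures. Peaks are not replicates, and p-values over peaks describe the lists compared.

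Peaks counted as shared when they overlapped by at least 1 bp. Regions found in both replicates are the bases called in both lists. The number of overlapping peaks was set against 1000 circular shifts of the list whose peaks were counted. Shifts ran along each chromosome, between the lowest start and the highest end over the 4 lists, and p is the one-sided share of shifts with as many overlaps. Scores of shared and unshared peaks were compared as mean differences of log2 score with two-sided permutation tests of 100000 resamples, in crossed replicate pairs whose lists share no IgG library. Pairs of equal and of crossed number were contrasted by the difference of mean log2 ratios, with 1000 bootstraps of 5 Mb segments, which for its alternatives also drew the error of the mean over shifts. Dense segments are those of 5 Mb in which both RECQ1 lists hold at least 4 times their median count per occupied segment. Segments were also picked from a single RECQ1 list by the same rule and measured in the other. Peaks outside chromosomes 1 to 22 and X were left out of segment counts and of named regions.

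Regions were named by a rule fixed before the data were examined: the 10 RECQ1 regions found in both replicates with the highest lower score of the replicates, the 10 such regions that also overlap ERα peaks of both replicates, and the 10 ERα regions by the same rule. Coordinates are 1-based on hg19. The rule also asked for nearest genes, for members of fixed gene lists and for 7 genes by name. The gene table used here is of GRCh38, so gene names, promoter shares, gene lists and sequence motifs, though planned, were not run.

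The design and most alternatives were fixed before the data were examined. The dense segments, their choice from a single list, leaving chromosome 22 out of the lists, the local shifts of 20 to 500 kb, the 2 kb distance, the score bins, the comparison at equal list size of the replicates, the chromosome comparison, the comparison of recurring with other RECQ1 peaks, the ERα score comparison and the use of column 8 were added afterwards. Alternatives planned in advance were an overlap of at least 50% of the shorter interval, the higher-scoring 50% of each list, random placement, peaks cut to 200 bp, leaving out chromosomes 17 and 20, the deposited shared list, leaving out each replicate, equal numbers of top peaks, the ERα list of equal number, and peaks of 1 kb or shorter.

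The overlap test was tested on simulated data with the 2536 peaks of RECQ1 replicate 1 against ERα replicate 2. Planted peaks aside, each peak was placed at random along its chromosome. The simulated lists thus lacked the crowding of the real list, and the test was not checked under such crowding. Of 40 simulated lists with no planted overlap, 2 had p under 0.05 and the mean ratio was 0.998; planted shares of 10% and 30% came back as 9.91% and 30.0%. For the score test in that list, 2 of 40 random splits had p under 0.05, and a planted log2 difference of 0.25 came back as 0.30 (SE 0.03). Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.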

Results

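The series mapped where RECQ1 and the estrogen receptor ERα sit on the genome of MCF-7 cells, an estrogen receptor-positive human breast cancer line. RECQ1, the product of the gene RECQL, is a DNA helicase of the RecQ family, enzymes that unwind DNA during repair and replication. ERα is a transcription factor that binds DNA when activated by estrogen. Chromatin was crosslinked, sheared and immunoprecipitated with an antibody against RECQ1, an antibody against ERα or control IgG, and the recovered DNA was sequenced. The 7 samples were 2 replicates of each of these immunoprecipitations and 1 input sample. Values came from 4 per-replicate peak lists, each holding the genomic intervals called as enriched over IgG, and from 1 deposited list of RECQ1 peaks shared between replicates. The antibody tag of RECQ1 replicate 1 names a histone-mark antibody, contrary to its title, which was followed here. Read depth was unknown for every sample, so the number of peaks in a list cannot be separated from how deeply its library was sequenced.

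ERα gave more peaks than RECQ1 in both replicates. The ERα lists held 11792 peaks in replicate 1 and 20178 in replicate 2, covering 5751 kb and 10557 kb. The RECQ1 lists held 2536 and 7023 peaks, covering 1130 kb and 3532 kb. Median peak width ran from 318 bp in RECQ1 replicate 1 to 406 bp in RECQ1 replicate 2, with 349 and 395 bp in the ERα lists. The largest peak score was 2845 and 2321 in the RECQ1 lists and 8087 and 6703 in the ERα lists.

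The first comparison asked how far the replicates of each factor located the same sites. For ERα, 6385 of 11792 replicate 1 peaks overlapped a replicate 2 peak, which is 54.1% (95% Wilson interval 53.2 to 55.0). For RECQ1, 671 of 2536 replicate 1 peaks did so, which is 26.5% (24.8 to 28.2). Seen from the longer lists, 31.6% of ERα replicate 2 peaks and 9.55% of RECQ1 replicate 2 peaks were found in replicate 1. Sites called in both replicates formed 6417 ERα regions with a median width of 305 bp and 672 RECQ1 regions with a median width of 249 bp.

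Both overlaps were far above chance placement. When a list was shifted along its chromosomes, a mean of 91.0 ERα peaks and 6.89 RECQ1 peaks overlapped, so the observed numbers were 70.2 and 97.4 times higher. Against shifts of only 20 to 500 kb the ratios were 45.5 for ERα and 29.1 for RECQ1, so the order of the factors turned. They were 183 and 233 in the higher-scoring 50% of each list and 141 and 174 with peaks cut to 200 bp, and counting RECQ1 peaks within 2 kb gave 20.9. No circular shift reached the observed numbers, and the one-sided permutation p was 0.001 for both, the smallest that 1000 shifts can give. Cutting every list to its 2536 top-scoring peaks, a choice made after the data were examined, put both factors on the same number of peaks. This kept every RECQ1 replicate 1 peak, weak ones included, but only the higher-scoring part of the other lists, so the shares cover unlike score ranges. At that size 75.3% of ERα replicate 1 peaks (73.6 to 76.9) and 18.8% of RECQ1 replicate 1 peaks (17.3 to 20.3) were found in the other replicate.

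High-scoring peaks recurred far more often than low-scoring peaks. When each list was divided by score into 10 bins of equal size, 99.8% of ERα replicate 1 peaks and 91.3% of ERα replicate 2 peaks in the top bin were found in the other replicate, against 3.48% and 0.248% in the lowest bin. The top bin of the RECQ1 lists recurred at 66.1% in replicate 1 and 31.0% in replicate 2, against 2.77% and 0.855% in the lowest bin. The deposited list of shared RECQ1 peaks held 733 intervals, all of them replicate 1 peaks. Of these, 671 overlapped a replicate 2 peak and 62 did not, and all 733 lay within 2 kb of one.

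**Figure D1:**
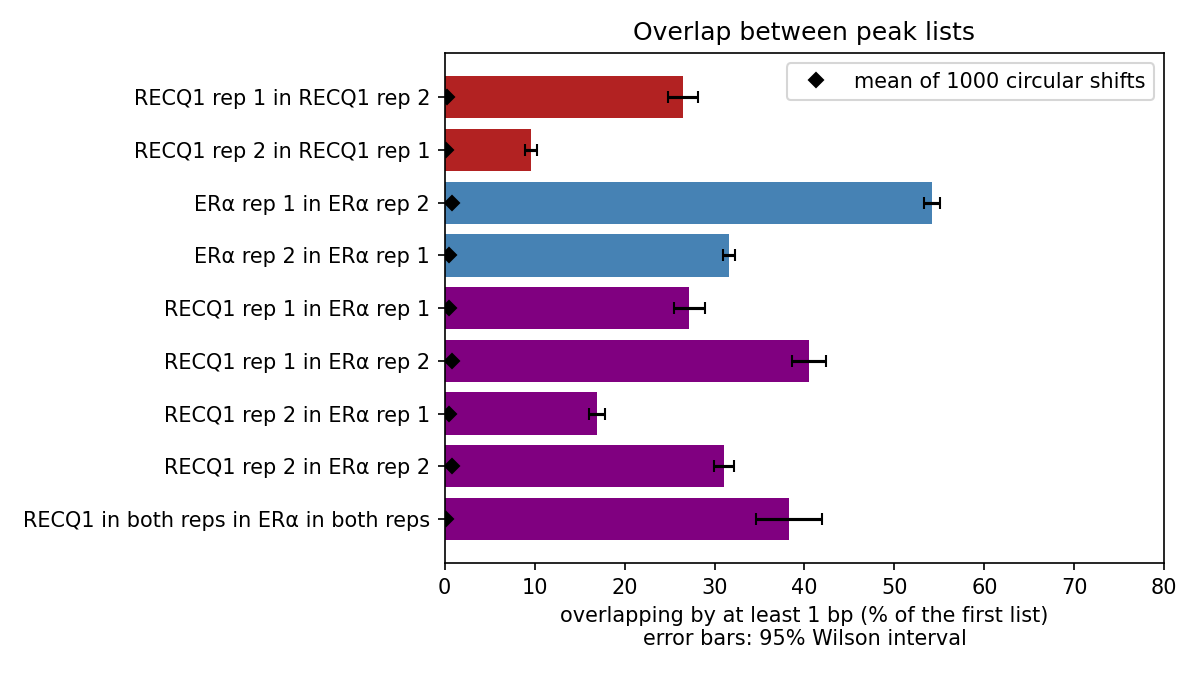
Share of peaks of the first-named list (horizontal axis, percent) that overlapped the second by at least 1 bp, with 95% Wilson intervals as error bars; red bars compare the RECQ1 replicates, blue bars the ERα replicates and purple bars RECQ1 with ERα. Diamonds mark the mean share in 1000 circular shifts, which stayed under 1% in every pair while the observed shares ran from 9.55% to 54.1%.

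The strongest RECQ1 sites lay in stretches of chromosomes 17 and 20 that were dense in RECQ1 peaks. Of the 10 RECQ1 regions with the highest lower score of the replicates, 9 lay on chromosome 20 and 1 on chromosome 17. The highest was at 59313181 to 59313602 on chromosome 17 (hg19), with scores of 2122 and 1813 in replicates 1 and 2. On chromosome 20, the next were at 52740413 to 52741092 (1796 and 2094), at 52238316 to 52240237 (1762 and 2205) and at 46093315 to 46093545 (1722 and 2321). All 10 overlapped an ERα peak in at least 1 replicate, and 5 overlapped ERα peaks of both replicates, the 4 named here among them. Genes at these positions were not assigned, because the gene table used here follows another genome build.

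The RECQ1 regions that overlapped ERα peaks of both replicates were led by these 5. Ranked by RECQ1 score, the top 10 of these comprised 8 on chromosome 20 and 2 on chromosome 17. Beyond the 4 already named, they included 52486019 to 52487133 on chromosome 20 (RECQ1 scores 1618 and 1911), 46121950 to 46122930 on chromosome 20 (1375 and 1825) and 57922367 to 57924063 on chromosome 17 (1282 and 1747).

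The strongest ERα sites lay elsewhere, and most of the 10 top regions lacked RECQ1. The 10 top ERα regions were led by 64200888 to 64201432 on chromosome 6 (scores 7418 and 6703), 100252964 to 100253625 on chromosome 2 (6712 and 6265) and 11588095 to 11588630 on chromosome 8 (8087 and 6164). None of the 10 overlapped RECQ1 peaks of both replicates, and 1 overlapped a RECQ1 peak of 1 replicate, at 69329984 to 69330517 on chromosome 11 (ERα scores 6048 and 6676). Of all ERα regions found in both replicates, 79.0% met no RECQ1 peak, so these 10 do not set the strongest sites apart. Over all ERα peaks the share with a RECQ1 peak rose with the ERα score, to 23.3% and 16.3% in the top bin of replicates 1 and 2.

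RECQ1 peaks crowded into 10 segments of 5 Mb, a pattern found and defined after the data were examined. These lay at 105 to 110 Mb of chromosome 1, 60 to 65 Mb of chromosome 3, 25 to 30 Mb of chromosome 6, 105 to 110 Mb of chromosome 7, 100 to 105 and 125 to 130 Mb of chromosome 8, 50 to 55 Mb of chromosome 15, 55 to 60 Mb of chromosome 17, and 45 to 50 and 50 to 55 Mb of chromosome 20. Together they made up 1.70% of the genome span covered by the lists. They held 14.5% of RECQ1 replicate 1 peaks (95% Wilson interval 13.1 to 15.9), 10.5% of RECQ1 replicate 2 peaks (9.76 to 11.2) and 24.3% of the RECQ1 regions found in both replicates (21.2 to 27.6). The corresponding ERα shares were 4.07% (3.73 to 4.45), 6.22% (5.90 to 6.56) and 3.92% (3.47 to 4.42), also above the span but lower than the RECQ1 shares by more than counting error. Because the segments were picked by their RECQ1 counts, the RECQ1 shares are raised by that choice. In segments picked from the other RECQ1 list alone, the density was 8.01 times that predicted by the span in RECQ1 replicate 1 (7.30 to 8.78) and 4.28 times in RECQ1 replicate 2 (4.05 to 4.52).

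**Figure D2:**
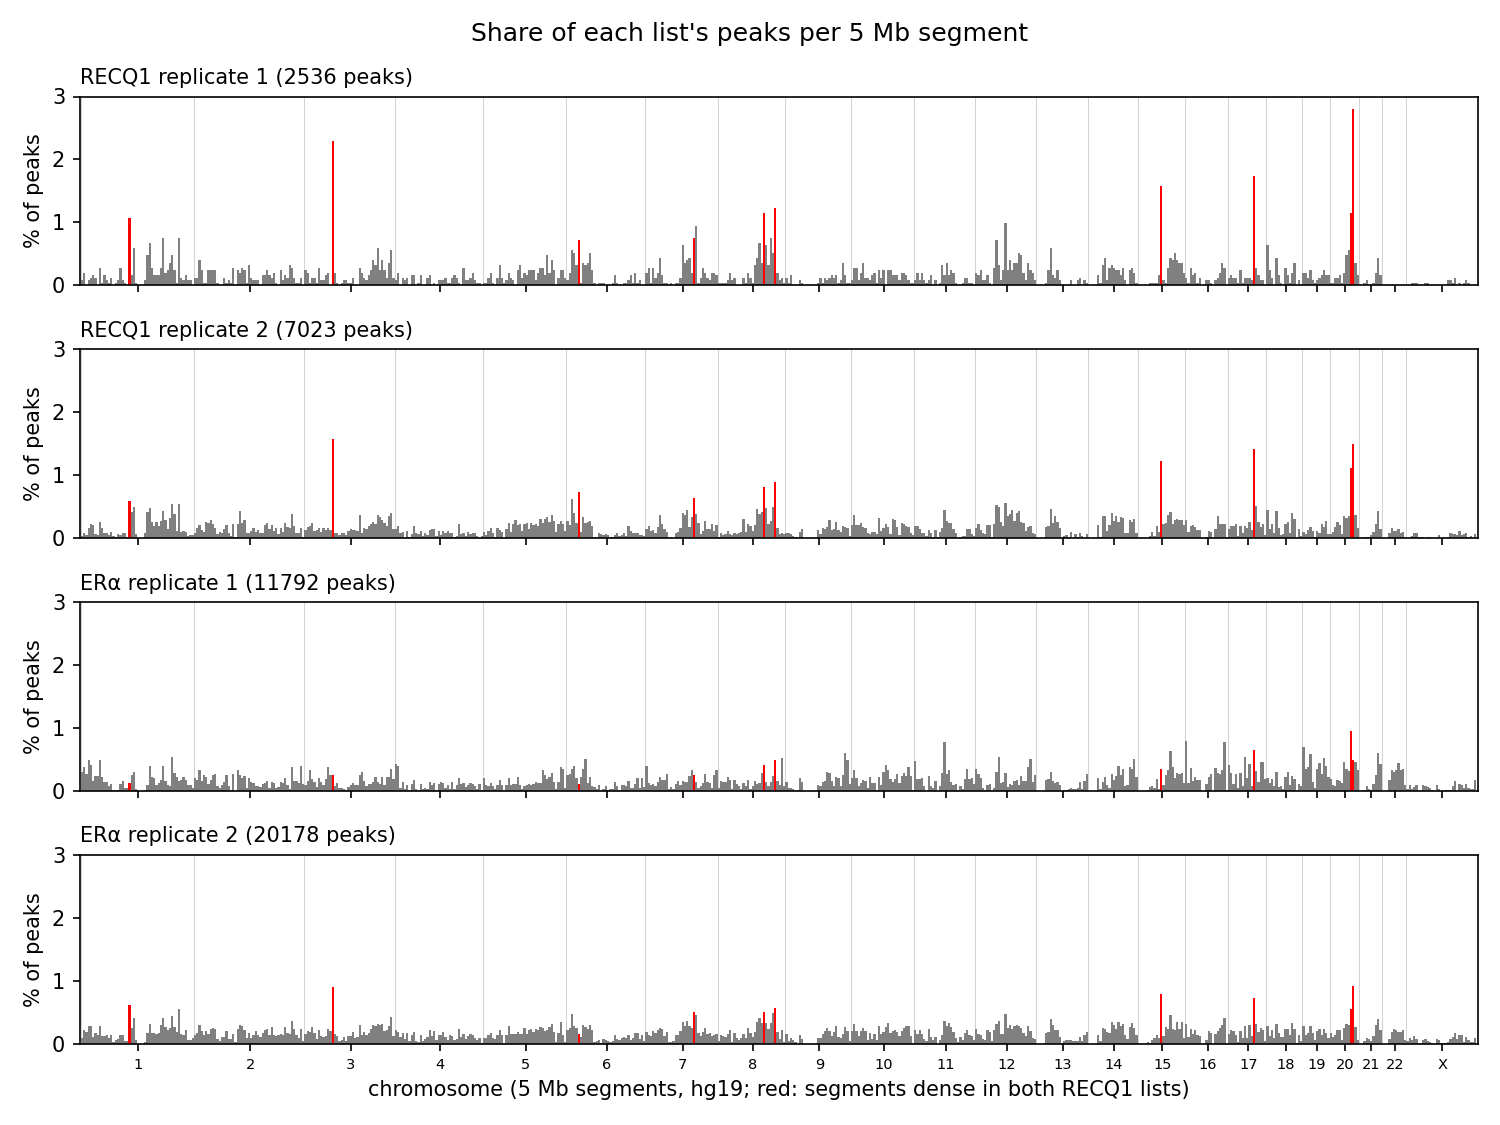
Share of each list's peaks (vertical axes, percent) in each 5 Mb segment along chromosomes 1 to 22 and X (horizontal axis, hg19), with 1 panel per peak list. Red bars are the 10 segments where both RECQ1 lists were dense; the tallest in RECQ1 replicate 1, at 50 to 55 Mb of chromosome 20, held 2.80% of RECQ1 replicate 1 peaks and 0.492% of ERα replicate 1 peaks.

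Chromosomes also differed between the factors. Of the 672 RECQ1 and 6417 ERα regions found in both replicates, 9.23% and 3.87% lay on chromosome 20 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 23 chromosomes, p = 1.67e-07). Chromosome 16 held 1.04% of RECQ1 and 4.88% of ERα regions (adjusted p = 2.61e-06, same exact test). In the single lists this gap was large in replicate 1 only. Chromosome 16 held 2.17% of RECQ1 and 4.58% of ERα peaks in replicate 1, and 2.58% and 2.98% in replicate 2. No RECQ1 region found in both replicates lay on chromosome X, where ERα had 116, although the RECQ1 lists had 18 and 68 peaks there. On chromosome 22 none was possible, because RECQ1 replicate 1 listed no peak there while replicate 2 listed 55, so its test does not compare the factors. With chromosome 22 counted, 5 chromosomes held a larger and 7 a smaller share of RECQ1 than of ERα regions at an adjusted p under 0.05. With the dense segments left out, 2 held a larger and 4 a smaller share, and 4 chromosomes, with 22 among them, passed in both tests. Of the 62 RECQ1 regions on chromosome 20, 19 and 36 lay in its dense segments at 45 to 50 and 50 to 55 Mb. Its RECQ1 excess lay in them: outside the dense segments chromosome 20 held 1.375% of RECQ1 and 2.481% of ERα regions (adjusted p = 0.189, same exact test). Because the dense segments were picked by RECQ1 counts, leaving them out tends to lower the RECQ1 share of a chromosome rich in them. How far the fall in differing chromosomes comes from that choice was not tested. Regions are not replicates, so these tests describe the lists, and the chromosomes were compared after the data were examined.

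The central comparison asked whether RECQ1 sits where ERα sits. Most RECQ1 regions overlapped an ERα peak in some replicate, whereas most ERα regions met no RECQ1 peak. The ERα lists are longer, with 11792 and 20178 peaks against 2536 and 7023 for RECQ1, so a RECQ1 region had more peaks to meet. By number, the 672 RECQ1 regions could not reach most of 6417 ERα regions, but the peaks of both RECQ1 lists could. How much of the contrast comes from list length was not tested. Of the 672 RECQ1 regions found in both replicates, 257 overlapped an ERα region found in both replicates, which is 38.2% (95% Wilson interval 34.6 to 42.0). A further 195 regions (29.0%) met a peak of ERα replicate 2 only, 22 (3.27%) met a peak of ERα replicate 1 only, and 198 (29.5%) met none. Seen from ERα, 256 of 6417 regions (3.99%) overlapped such a RECQ1 region, and 5068 (79.0%) met no RECQ1 peak of either replicate.

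Shifted lists gave a mean of 1.31 overlapping RECQ1 regions (SD 1.16 over shifts) and at most 7, so the observed 257 was 196 times the mean. The one-sided permutation p was 0.001, the smallest that the shifts can give. Against shifts of 20 to 500 kb the ratio was 83.0, and with peaks cut to 200 bp it was 394. The ratio depended on the libraries used: it was 67.8 without RECQ1 replicate 1, 105 without RECQ1 replicate 2, 92.4 without ERα replicate 1 and 101 without ERα replicate 2. The shares were then 14.8%, 22.4%, 67.3% and 41.5%.

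RECQ1 peaks that recurred between replicates met ERα more often than those that did not, a comparison added after the data were examined. Of RECQ1 replicate 1 peaks also found in replicate 2, 67.5% (453 of 671) overlapped an ERα replicate 2 peak, against 30.7% (573 of 1865) of the others. For RECQ1 replicate 2 peaks against ERα replicate 1, the shares were 42.3% (284 of 671) and 14.2% (904 of 6352). The odds ratios were 4.69 and 4.42 by Fisher's exact test, two-sided, over peaks (p = 8.61e-62 and 3.12e-61). Recurrence and overlap with ERα both rose with the RECQ1 score, and peaks were not matched for score. A link of recurrence itself to ERα can therefore not be told apart from score. Recurring peaks were also called against the IgG library of the ERα list they were compared with.

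Each RECQ1 list overlapped each ERα list. Lists of equal replicate number were called against the same IgG library, so the crossed pairs share no control. In the crossed pairs, 1026 of 2536 RECQ1 replicate 1 peaks (40.5%, 38.6 to 42.4) overlapped ERα replicate 2 and 1188 of 7023 RECQ1 replicate 2 peaks (16.9%, 16.1 to 17.8) overlapped ERα replicate 1. In the pairs of equal number, the overlaps were 689 peaks (27.2%, 25.5 to 28.9) for replicate 1 and 2182 peaks (31.1%, 30.0 to 32.2) for replicate 2. Against shifted lists the crossed pairs were 52.5 and 38.5 times higher and the equal pairs 63.2 and 39.4 times higher, each with a permutation p of 0.001, the smallest possible. The mean log2 ratio of the equal pairs exceeded that of the crossed pairs by 0.15 (95% block bootstrap interval 0.11 to 0.20). With the same number of top-scoring peaks in every list the difference was -0.07 (-0.15 to 0.0037), an interval that includes 0.

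At equal list size, RECQ1 replicate 1 met the other RECQ1 list more often than it met either ERα list. For RECQ1 replicate 2 no such difference passed the test, and the replicates were not tested against each other. Among its 2536 peaks, RECQ1 replicate 1 had 476 (18.8%) found in RECQ1 replicate 2, 289 (11.4%) in ERα replicate 1 and 389 (15.3%) in ERα replicate 2. The exact binomial test on peaks found in one list only gave adjusted p = 1.22e-16 and 0.000214, over 4 tests. Of the 2536 top peaks of RECQ1 replicate 2, 476 were found in RECQ1 replicate 1, 430 in ERα replicate 1 and 497 in ERα replicate 2, with adjusted p = 0.0996 and 0.415 by the same exact test. In the full lists, which differ in length, the order for RECQ1 replicate 1 turned. There 26.5% of its peaks were found in RECQ1 replicate 2, 27.2% in ERα replicate 1 and 40.5% in ERα replicate 2. The cut kept a smaller part of each ERα list than of RECQ1 replicate 2, so the difference at equal size cannot be told apart from the cut.

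RECQ1 peaks that overlapped ERα scored higher than those that did not. In RECQ1 replicate 1, peaks shared with ERα replicate 2 had a median score of 357 against 282, a mean difference of 0.33 on the log2 scale (SE 0.02 over peaks). In RECQ1 replicate 2, peaks shared with ERα replicate 1 had a median of 470 against 313, a difference of 0.56 (SE 0.02). The two-sided permutation p was 1e-05 in both lists, the smallest that 100000 resamples can give. With the ERα list of equal number the difference in RECQ1 replicate 2 was 0.35, over 1.5 times smaller.

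ERα peaks with a RECQ1 peak also scored higher than those without, in a comparison added after the data were examined. In ERα replicate 1 the median score was 587 with a RECQ1 replicate 2 peak and 306 without, a difference of 0.82 on the log2 scale (SE 0.03). In ERα replicate 2 it was 783 with a RECQ1 replicate 1 peak and 305 without, a difference of 1.16 (SE 0.04). Both permutation p values were 1e-05, the smallest possible. From the lowest to the highest score bin of ERα replicate 1, the share of peaks with a RECQ1 replicate 2 peak went from 0.848% to 23.3%. In ERα replicate 2 the share with a RECQ1 replicate 1 peak went from 0.149% to 16.3%. The RECQ1 lists behaved alike, with shares going from 15.8% to 65.0% in replicate 1 and from 1.14% to 39.5% in replicate 2.

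**Figure D3:**
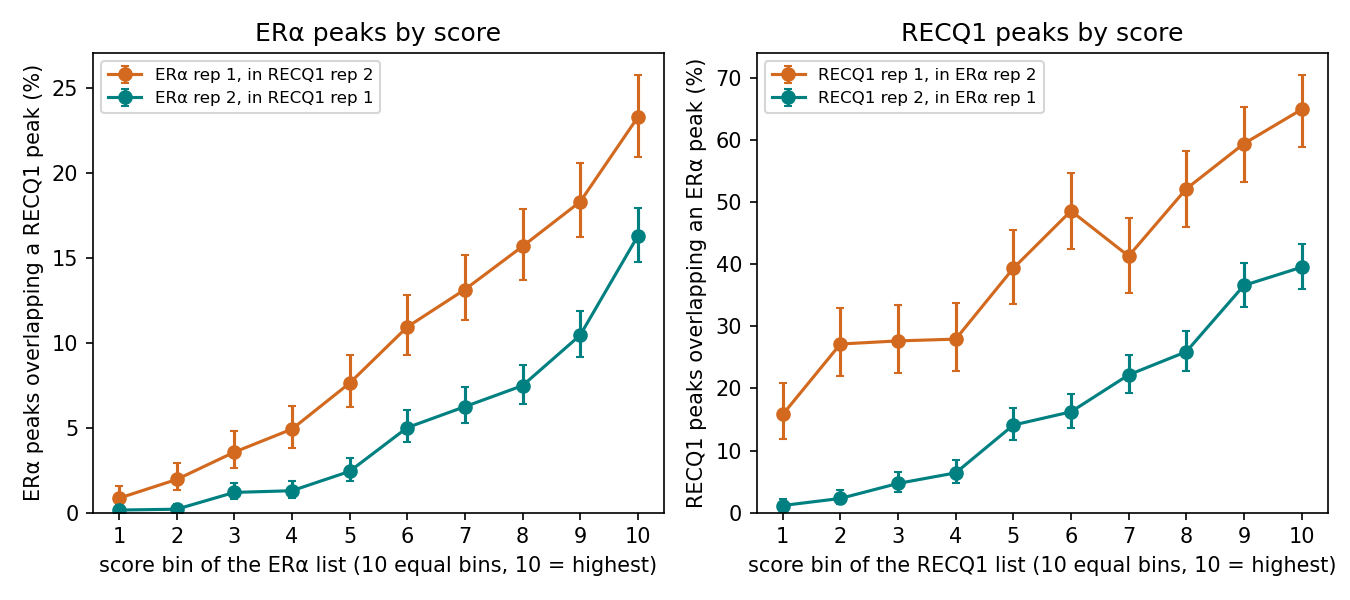
Share of peaks that overlapped the other factor (vertical axes, percent, with 95% Wilson intervals) by score bin (horizontal axes, 10 bins of equal size, 10 highest), for ERα peaks on the left and RECQ1 peaks on the right, in crossed replicate pairs. The share was highest in the top bin of every list, reaching 23.3% and 16.3% for ERα and 65.0% and 39.5% for RECQ1.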

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

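The tests of DNA copies, of RECQ1 following ERα, of the IgG library of replicate 1 and of the shared IgG library, and the comparisons with equal numbers of ERα peaks and without chromosome 22, were chosen after the results they bear on were seen.

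Some peaks lay outside chromosomes 1 to 22 and X, in sequences that the segment counts and named regions left aside: 4 in RECQ1 replicate 1, 10 in ERα replicate 1 and 11 in ERα replicate 2, against 0 in RECQ1 replicate 2. On a single unplaced contig, Un_gl000220, lay 3, 7 and 7 of them, and 2 of the ERα replicate 2 peaks were mitochondrial. RECQ1 replicate 1 had 0 of its 2536 peaks on chromosome 22, where RECQ1 replicate 2 had 55 of 7023 (0.783%), so that 19.9 were predicted (Fisher's exact test, two-sided, p = 7.9e-08), and the ERα lists had 274 and 269.

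RECQ1 peaks were concentrated in 10 segments of 5 Mb, at 8.49 and 6.14 times the density that their span predicts. RECQ1 peaks that overlapped no ERα peak were still denser than the span predicts, in segments picked from the other RECQ1 list. The density was 3.68 times in the lower replicate (95% interval 3.42 to 3.96). Called ERα peaks alone thus do not account for the concentration. ERα binding without a called peak could, so RECQ1 following ERα stays open. Extra DNA copies, known for parts of chromosomes 1, 3, 17 and 20 in MCF-7, may contribute. Both ERα lists were denser in the 10 segments too, 2.39 times in the lower list over all together and beyond counting error in 8 of them singly. This cannot tell copies from co-location, because the segments were picked by RECQ1 counts and RECQ1 and ERα peaks overlap. In the segment on chromosome 6 neither ERα list showed an excess, the higher ERα ratio being 0.902 (95% interval 0.636 to 1.28). A gained segment with few ERα sites could give such a ratio, so extra copies stay open there too. Copy number was not measured. A preference of RECQ1 itself for these segments would explain its excess over ERα, but picking segments by RECQ1 counts also raises that excess. Such a preference stays open and untested.

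ERα replicate 1 had 16.2% of its peaks on chromosomes 16, 17, 19 and 22 together, against 10.0% in replicate 2, a ratio of 1.62 (95% interval 1.53 to 1.72). The IgG library of replicate 1 is argued against, since RECQ1 replicate 1, called against the same IgG, had no larger share than RECQ1 replicate 2: the ratio was 0.816 (0.699 to 0.953), and 0.885 (0.757 to 1.03) with chromosome 22, on which RECQ1 replicate 1 lists no peak, left out of the lists. Weak peaks near the calling threshold may account for part: in the higher-scoring 50% of each list the ratio was 1.28 (1.19 to 1.38), between the bounds set beforehand for and against, and with 2536 top peaks each it was 1.16 (1.02 to 1.32), so this stays open. Weak peaks differed between the lists: those of replicate 2 missing from replicate 1 had a share of 7.02% and a median score of 237, whereas 867 of the 5407 of replicate 1 missing from replicate 2 lay there, with a median score of 217, and peaks found in both had 16.4% in either list. No biological explanation was tested, since both lists are of the same group.

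RECQ1 and ERα peaks overlapped far above chance. The shared IgG library as the whole cause is argued against, since crossed pairs, which share none, overlapped far more often than shifted lists, 38.5 times in the lower pair. Both lists being dense in the same regions is argued against too, because shifts of only 20 to 500 kb left the observed number 83.0 times higher. A candidate explanation is that ERα-bound sites draw RECQ1 or its antibody. ERα peaks with a RECQ1 peak scored higher, by 0.82 on the log2 scale in the lower list and by 0.76 there when compared within 5 Mb segments. Among the 10 top ERα regions 1 had any RECQ1 peak, while 79.0% of all ERα regions had none, so these 10 are too few to weigh either way. Signal that open chromatin gives with any antibody would also raise the overlap, and it stays untested without a list for another factor.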

How the results depend on the processing

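Local shifts, leaving out the dense segments, the 2 kb distance, permutation within segments, column 8, picking segments from a single list, leaving out chromosome 22, the replicate block and the ERα score comparison were chosen after the results were seen. Of 50 alternatives, 47 kept direction and side of the threshold or, without a test, stayed within the 95% interval. These 47 include the replicate block for the values per list, whose outcome was fixed in advance and adds no support. The density of RECQ1 replicate 2 in dense segments moved from 6.14 to 4.28 in segments picked from replicate 1 alone, which were 21 in place of 10. Without chromosome 22 the ratio of RECQ1 shares on chromosomes 16, 17, 19 and 22 was 0.885 (exact p = 0.129) in place of 0.816 (p = 0.00986). The pairing contrast went from 0.15 to -0.0695 with equal numbers of top peaks, with an interval of -0.15 to 0.0037 that includes 0, and was 0.13 with an overlap of at least 50%; the cause was not tested. Ratios to shifted lists ran from 20.9 to 233 over 8 alternatives for the RECQ1 replicates, from 45.5 to 183 over 7 for the ERα replicates and from 67.8 to 394 over 12 for RECQ1 against ERα, where leaving out 1 replicate gave 67.8 to 105. Score differences ran from 0.24 to 0.36 and from 0.35 to 0.64 for the RECQ1 lists over 5 alternatives each, and from 0.76 to 0.80 and from 1.11 to 1.18 for the ERα lists over 2 each. No paired analysis was possible for the overlaps, because they come from no test over libraries. For values per list, the replicate number as a block left the log2 difference of RECQ1 minus ERα, which a block cannot move here, at -1.87 for the number of peaks (SE 0.35 with the block, 0.83 without), at 0.53 for the share on chromosome 20 (SE 0.04 and 0.20) and at -0.64 for that on chromosome 16 (SE 0.43 and 0.33). With 2 pairs no exact test can go below 0.5, so none was called. Lists of equal number are paired by their IgG library. Deviations of same-numbered lists across 22 chromosomes gave Pearson's r of -0.08 and Spearman's rho of -0.24. These showed no positive link of chromosome shares, but they cannot show that the shared IgG library has no effect. A replicate cannot be left out of a comparison of 2 replicates. The planned promoter shares, gene lists and motifs, with their alternatives, were not run for want of an annotation and sequence of hg19 in the sources used here. Depth was unknown, so list length and absence of a peak cannot be set against sequencing effort.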

Other observations

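The segments were chosen, and their densities computed, after the data were examined. The 10 segments dense in RECQ1 peaks differed in how far ERα shared their density, given here as the ratio to the density that the span predicts, for replicates 1 and 2 in turn. At 50 to 55 Mb of chromosome 20 the RECQ1 ratios were 16.5 and 8.78 and the ERα ratios 2.89 and 5.41. At 60 to 65 Mb of chromosome 3, which is 0.170% of the span, lay 2.29% and 1.57% of RECQ1 peaks and 0.254% and 0.907% of ERα peaks. At 45 to 50 Mb of chromosome 20 the ratios were 6.72 and 6.52 for RECQ1 and 5.63 and 3.20 for ERα. At 25 to 30 Mb of chromosome 6, RECQ1 stood at 4.17 and 4.26 (95% Wilson intervals 2.64 to 6.58 and 3.25 to 5.60), while ERα stood at 0.598 and 0.902 (0.342 to 1.05 and 0.636 to 1.28). At 105 to 110 Mb of chromosome 1 the ERα replicates themselves differed, with 15 and 123 peaks and ratios of 0.747 and 3.58, beside 6.26 and 3.43 for RECQ1.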
